A study of Mus musculus with 6 samples.

How the data were processed

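Liver RNA from 3 samples of mice given a control shRNA adenovirus and 3 samples of mice given a Tox4 shRNA adenovirus was enriched for poly-A RNA and sequenced as paired 100 bp reads, per the labels. The dose was 2.5e+08 particles per gram in C57BL/6 mice labelled as 10 weeks old. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0 and limma 3.44.3 without saying what each did, and name both the GRCm38 and GRCh38 builds. All 113193 transcript identifiers in the count table are mouse identifiers, and the transcript set is not given in the sources used here.

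The authors deposited 3 kinds of values. The estimated counts per transcript were made with kallisto by the authors and are given as whole numbers without scaling. The deposited TPM values, 1 per gene symbol for 34945 symbols, sum to between 986197 and 990244 per sample, and how transcripts were joined into genes is not stated. The table of changed genes deposited by the authors gives a log2 fold change, a mean log2 expression and an unadjusted p-value per gene under limma's column names. Its model, filter and threshold are not stated. Every per-sample column was matched to its sample through the sample descriptions, with 0 columns left unmatched.

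Estimated counts were summed per gene by joining transcripts to GENCODE release M21 on their identifiers without version. Of the 113193 transcripts, 111450 were joined, which held 99.2% to 99.4% of the counts of each library, and gave 35150 genes, of which 20520 had a count above 0. Gene sums were rounded to whole numbers. Read alignments were not analysed here, so the assignment of reads among closely related genes is that of the deposited counts. Library totals ran from 21946741 to 34761762 estimated counts, and between 13348 and 14436 genes per library had at least 10 counts. No pair of libraries of a group was a copy of another: identical counts made up 0.525% to 1.09% of genes, and the chi-square per gene between replicates was 25.7 to 44.7. The replicate numbers showed no clear pairing across groups, with 3 of 6 libraries closest to the library with the same number. With 3 libraries per group this cannot exclude a shared batch, and no label says that the numbers mark one. They were used as a block only in an alternative.

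Genes were tested in R 4.3.3 with edgeR 4.0.16, using the filterByExpr filter, TMM scaling, and glmQLFit with robust=TRUE, with the group as the single term and a two-sided quasi-likelihood test. A Benjamini-Hochberg adjusted p under 0.05 over 13889 genes counted as a change. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values are library-scaled counts (edgeR cpm after TMM) with no prior count, and errors on them are SDs over 3 libraries. The same fit was run on 35517 transcripts. With 3 livers per group, p-values rest on the variance that edgeR pools across genes.

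Before the data were examined, 29 lists with 406 genes were written for functions of the fasted liver, for stress and immune responses, and for 9 other cell types that a piece of liver could hold. List symbols not found in the annotation numbered 2. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists. Camera compares a list with the other genes. It was also run with a correlation estimated per list, and fry was run in its place, which asks whether the genes of a list move one way on balance and compares them with no other genes. Members were counted by the edgeR test, adjusted over all genes and adjusted over the list alone.

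The genes named were set by a rule before the data were examined. Tox4 and 11 genes of glucose output and insulin signalling were named whatever their result. Then came the 12 largest increases and 12 largest decreases among genes that passed, had groups that did not overlap and a mean of at least 1 CPM, leaving out predicted genes and antigen receptor segments. Last came up to 4 members with the smallest p from each list.

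The alternatives set in advance were DESeq2 size factors, library size alone, no filter beyond a count above 0, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, robust=FALSE, a replicate block, each library left out in turn, and limma on log2 TPM with a pseudocount of 1 or 0.1, or with no filter. Thresholds of 0.01 and 0.1 and a fold of at least 1.5 were also tried, and camera was run on voom weights, on log2(TPM + 1) and with a prior count of 0.5. Thinning all libraries to the smallest total was added after the data were seen. The deposited table of changed genes was compared with the edgeR test by gene symbol.

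The tests were run on simulated data in which 200 genes had been changed by a known fold. EdgeR found 43.9% of genes changed 1.5-fold, 70.8% changed 2-fold and 96.9% changed 4-fold, with 5.5% of its calls false. DESeq2 made 13.2% false calls there, limma voom 4.5% and limma on log2 values 4.4%.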

Results

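Messenger RNA was measured in 6 liver samples of fasted C57BL/6 mice. Per the labels, 3 samples belong to an adenovirus carrying a control shRNA and 3 to an adenovirus carrying an shRNA against Tox4, a chromatin-bound HMG-box protein known as a partner of protein phosphatase 1. The virus was given into the tail vein, the mice were fasted for 16 h from day 9, and livers were taken on day 10. The labels do not say whether each sample is a separate mouse, and 1 shRNA virus per group was used. Estimated counts summed to 27736175, 29044842 and 21946741 in control shRNA replicates 1, 2 and 3, and to 32572662, 26161218 and 34761762 in Tox4 shRNA replicates 1, 2 and 3. The 10 most abundant genes took 20.3%, 18.9% and 20.4% of the counts in control livers and 17.6%, 18.3% and 17.8% in Tox4 shRNA livers. TMM scaling factors, which set the level of no change, were 0.910, 0.971 and 0.913 in the control group and 1.07, 1.04 and 1.11 in the Tox4 shRNA group. Fold changes are Tox4 shRNA relative to control shRNA on that scale unless another is named. Scaling by library size alone raised the median log2 fold change of all tested genes by 0.21, and the deposited TPM values raised it by 0.23.

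The first question was how far the shRNA lowered its target. Tox4 (ENSMUSG00000016831.12, GRCm38 chromosome 14, 52279146 to 52296401, plus strand) fell from 37.3 ± 2.90 to 25.7 ± 3.80 CPM (mean ± SD, n = 3 per group). Its log2 fold change was -0.54 (SE 0.11, edgeR adjusted p = 0.0257), a change of -31.1%, and it was lower in 3 of 3 Tox4 shRNA livers than in any control liver. The single libraries held 40.3, 37.2 and 34.5 CPM in control livers and 29.5, 25.9 and 21.9 CPM in Tox4 shRNA livers. In the deposited TPM values the groups overlapped, with 8.84, 8.99 and 7.53 TPM in control livers against 8.06, 6.999 and 6.28 TPM in Tox4 shRNA livers. The most abundant Tox4 transcript, ENSMUST00000022766.7, had a log2 fold change of -0.55 (SE 0.13) that did not pass among all transcripts (edgeR adjusted p = 0.258). The Tox4 call was lost without control replicate 1 (-0.48, adjusted p = 0.0903), control replicate 2 (-0.54, 0.0836) or Tox4 shRNA replicate 3 (-0.43, 0.0662), with scaling by library size (-0.33, 0.0534) and on log2(TPM + 1) (-0.22, limma adjusted p = 0.213). Its value stayed negative in all 18 alternative fits, from -0.65 to -0.22, with adjusted p from 0.00216 to 0.312.

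**Figure D1:**
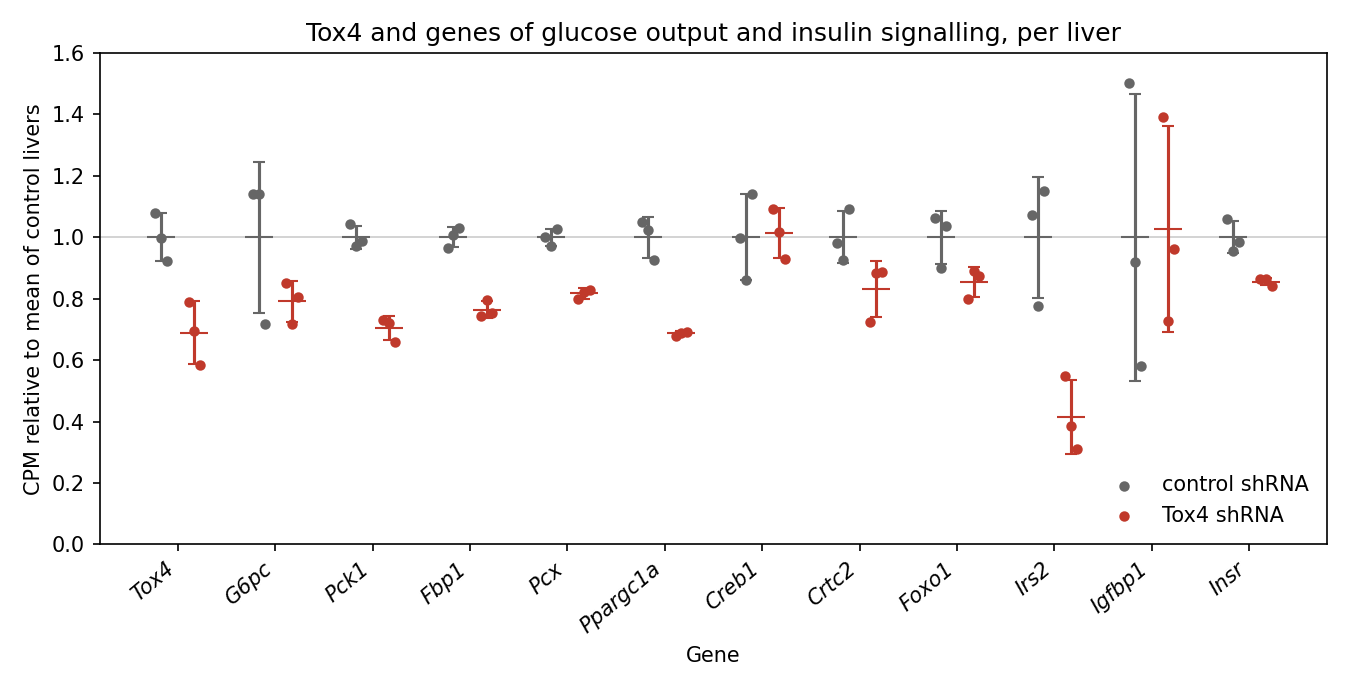
CPM of the 12 genes named in advance, each divided by its control mean, in each of the 6 livers (points) with the group mean and SD (bars). Tox4, Pck1, Fbp1, Ppargc1a and Irs2 passed the edgeR test, and for each of them all 3 Tox4 shRNA livers lay below all 3 control livers.

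The glucose-producing program of the fasted liver and its regulators were examined next. Pck1, the enzyme that makes phosphoenolpyruvate from oxaloacetate, fell from 4109.5 ± 154 to 2894 ± 157 CPM (n = 3 per group, log2 fold change -0.51, SE 0.10, edgeR adjusted p = 0.0202). Fbp1, the fructose-1,6-bisphosphatase of gluconeogenesis, fell from 664 ± 21.7 to 507 ± 18.8 CPM (-0.39, SE 0.08, adjusted p = 0.0272). Ppargc1a, a coactivator induced in the liver by fasting, fell from 31.8 ± 2.10 to 21.8 ± 0.247 CPM (-0.54, SE 0.08, adjusted p = 0.0105). Irs2, an adaptor of the insulin receptor, fell from 20.5 ± 4.07 to 8.53 ± 2.49 CPM (-1.26, SE 0.23, adjusted p = 0.0299). G6pc, the catalytic subunit of glucose-6-phosphatase, was 259.9 ± 63.7 CPM in control and 206 ± 17.6 CPM in Tox4 shRNA livers and did not pass (-0.34, SE 0.18, adjusted p = 0.317). It passed without control replicate 3 (-0.53, adjusted p = 0.0327), and its adjusted p over all alternatives ran from 0.0327 to 0.932. The pyruvate carboxylase gene Pcx (-0.29, adjusted p = 0.0546) and the insulin receptor gene Insr (-0.22, 0.0987) did not pass either. Nor did the transcription regulators Crtc2 (-0.27, 0.144), Foxo1 (-0.23, 0.153) and Creb1 (0.02, 0.931) or the FoxO1 target Igfbp1 (0.04, 0.975). Crtc2, Foxo1 and Insr turned to 0.03, 0.04 and 0.09 on log2(TPM + 1), and Creb1 and Igfbp1 turned negative without some single libraries, to -0.07 for Creb1 without control replicate 2 and -0.24 for Igfbp1 without Tox4 shRNA replicate 1.

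Ppargc1a kept its call whichever library was left out. The Pck1 call was lost without control replicates 1, 2 or 3 or Tox4 shRNA replicate 3 (adjusted p up to 0.0761). Fbp1 lost its call in 5 of 6 such fits, all but the one without Tox4 shRNA replicate 2 (adjusted p up to 0.0906). Irs2 lost its call without control replicates 1 or 3 or Tox4 shRNA replicates 2 or 3 (adjusted p up to 0.0921), and with no filter beyond a count above 0 (0.0561). With scaling by library size the log2 fold changes were -0.30 for Pck1, -0.18 for Fbp1, -0.34 for Ppargc1a and -1.05 for Irs2, and the Fbp1 call was lost. On log2(TPM + 1) they were -0.24, -0.12, -0.16 and -0.73, where Pck1, Fbp1 and Ppargc1a lost their calls while Irs2 kept its own, and with no filter on that scale Irs2 lost it too (0.0867).

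Across the liver, 757 of 13889 genes tested (5.45%) changed in the edgeR test, 368 upwards and 389 downwards, and 3096 had an unadjusted p under 0.05. The changes were mostly small: the median size of the log2 fold change among the 757 genes was 0.54, and 81 genes rose and 12 fell at least 2-fold. In all 757 the CPM values of the groups did not overlap, which held for 3923 of all genes tested (28.2%) against the 10% that chance gives with 3 against 3. Abundant transcripts leaned downwards, with a median log2 fold change of -0.13 in the most abundant 10% of genes (31 up, 180 down) and 0.08 in the least abundant 10%. The split between directions rested on the scaling: library size alone gave 2327 up and 108 down, and limma on log2(TPM + 1) gave 1873 up and 43 down. Leaving out a library gave 154 genes without control replicate 1, 172 without control replicate 2, 230 without control replicate 3, 477 without Tox4 shRNA replicate 1, and 284 without Tox4 shRNA replicate 3. DESeq2 called 1214 genes, of which 751 were shared with edgeR.

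**Figure D2:**
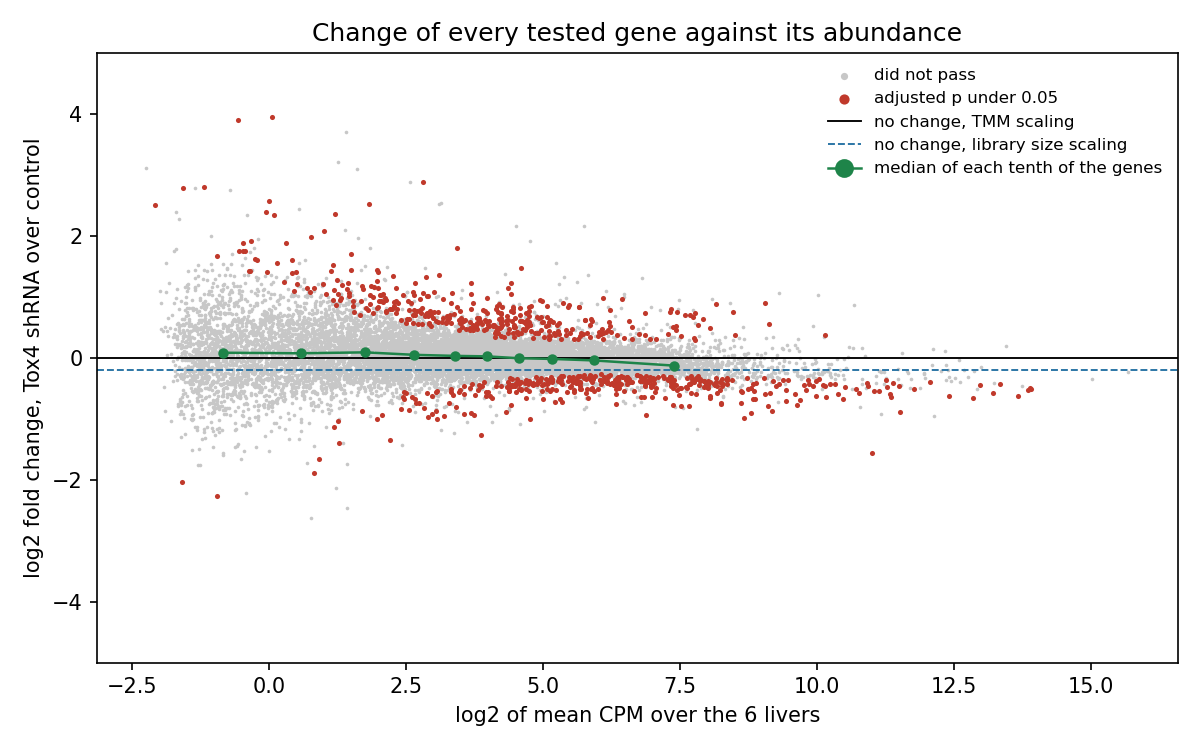
Log2 fold change of each gene tested (vertical axis) against its log2 mean CPM (horizontal axis), with called genes in red and the medians of 10 abundance bins in green. The black line is no change under TMM scaling and the dashed blue line no change under library-size scaling, and the green medians run from 0.08 in the least abundant bin to -0.13 in the most abundant.

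The largest increases named by the rule set in advance included Obp2a, a lipocalin of the odorant-binding family (GRCm38 chromosome 2, 25700043 to 25703326), at 1.03 ± 0.529 CPM in control and 6.05 ± 0.698 CPM in Tox4 shRNA livers (n = 3 per group, log2 fold change 2.53, SE 0.30, edgeR adjusted p = 0.00468). Phlda3, a p53 target that holds back Akt, rose from 0.754 ± 0.131 to 3.23 ± 0.841 CPM (2.09, SE 0.28, 0.00682). Dusp8, a phosphatase of MAP kinases, rose from 0.730 ± 0.334 to 3.87 ± 0.949 CPM (2.36, SE 0.33, 0.00724). Acta2, the smooth muscle actin of activated stellate cells, rose from 0.685 ± 0.152 to 2.71 ± 0.639 CPM (1.99, SE 0.30, 0.0104). The others were Sprr1a (3.95), Apol10b (2.89), the replication licensing factor Cdc6 (2.56), the small G protein Rasd1 (2.35), the ErbB ligand Nrg1 (1.88), the adhesion receptor Adgrv1 (1.80), the cytokine signal suppressor Socs1 (1.70) and the recombination helicase Rad54l (1.6). Sprr1a had no reads in control replicate 3 and a control mean of 0.118 CPM, so the size of its fold is poorly set, and it was 6.30 without control replicate 1. Control means were also low for Cdc6 (0.284 CPM), Rasd1 (0.354 CPM), Nrg1 (0.526 CPM) and Rad54l (0.652 CPM). Cdc6 and Rad54l did not pass in limma voom (adjusted p = 0.0589 and 0.0892). Of these 12 genes, 7, 5 and 9 kept their call without control replicates 1, 2 and 3, and 10, 11 and 11 without Tox4 shRNA replicates 1, 2 and 3. Obp2a, Phlda3, Dusp8 and Acta2 kept theirs in all 6 fits. All 12 kept it under scaling by library size, which moved all genes upwards alike and so is no test of an increase.

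Among the largest decreases, Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, fell from 3086 ± 798 to 1042 ± 240 CPM (n = 3 per group, log2 fold change -1.57, SE 0.23, edgeR adjusted p = 0.0196). Ugt2b1, a glucuronosyltransferase, fell from 540.0 to 273 CPM (-0.99, SE 0.20, 0.0433). Mfsd4b1, a member of the major facilitator family of transporters (GRCm38 chromosome 10, 40001575 to 40025268), fell from 36.2 ± 3.85 to 18.03 ± 0.90 CPM (-1.01, SE 0.10, 0.00442). Ugt1a10, which shares exons with the rest of the Ugt1a cluster, fell from 2.76 ± 0.142 to 0.754 ± 0.254 CPM (-1.88, SE 0.29, 0.0108). The remaining genes were Cnmd (-1.66), the AMP deaminase Ampd1 (-1.40), the SMN complex member Gemin4 (-1.35), Irs2, Galnt15 (-1.05), Lrit2 (-1.0), the prostaglandin D receptor Ptgdr (-1.0) and the GABA receptor subunit Gabbr2 (-0.96). Of the 12 genes, 5, 6 and 5 kept their call without control replicates 1, 2 and 3, and 9, 7 and 8 without Tox4 shRNA replicates 1, 2 and 3. Mfsd4b1 and Ugt1a10 kept theirs in all 6 fits, and all 12 did under scaling by library size.

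The gene lists set in advance were then compared, 29 in number, with camera at its preset correlation. Camera placed 7 lists lower in Tox4 shRNA livers, 6 of them of hepatocyte functions, and none of the 29 lists passed with an estimated correlation. Splits of the 6 libraries that mixed the groups called 2 to 11 lists at the preset correlation. A small camera p alone thus does not set the real groups apart. Of 13 gluconeogenesis genes, 3 fell and none rose, Pck1, Fbp1 and Ppargc1a (6 adjusted over the list alone), with a median log2 fold change of -0.29 (camera adjusted p = 0.00201, and adjusted p = 0.403 with an estimated correlation). Of 14 genes of bile acid synthesis and transport, 3 fell (4 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.00131, and 0.403 with an estimated correlation). Among them, the bile acid uptake carrier Slc10a1 fell from 580.4 to 311 CPM (-0.90, SE 0.11, edgeR adjusted p = 0.00481) and Slc27a5, the bile acid CoA ligase, and the uptake carrier Slco1b2 had log2 fold changes of -0.59 (SE 0.10, 0.0136) and -0.34 (SE 0.09, 0.0482). Of 17 xenobiotic metabolism genes, 6 fell (9 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.00281, and 0.403 with an estimated correlation), including the cytochrome P450 Cyp3a25, from 1599 ± 23.0 to 1065 ± 6.47 CPM (-0.59, SE 0.08, 0.00847). Of 16 urea cycle and amino acid breakdown genes, 2 fell (5 adjusted over the list alone), the histidine ammonia-lyase Hal (-0.75, SE 0.15, 0.0316) and the tyrosine pathway enzyme Hpd (-0.49, SE 0.12, 0.0390), with a median of -0.26 (camera adjusted p = 4.94e-04, and 0.497 with an estimated correlation). Of 24 fatty acid oxidation and ketogenesis genes, 1 fell (4 adjusted over the list alone), the carnitine palmitoyltransferase Cpt1a (-0.37, SE 0.09, 0.0424), with a median of -0.16 (camera adjusted p = 0.00201, and 0.577 with an estimated correlation). Of 14 hepatocyte identity genes, 2 fell (4 adjusted over the list alone), the transcription factor Cebpa (-0.36, SE 0.07, 0.0248) and the transthyretin gene Ttr (-0.48, SE 0.12, 0.0441), with a median of -0.22 (camera adjusted p = 0.00201, and 0.403 with an estimated correlation). No red cell gene of 5 passed (1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.0401, and 0.577 with an estimated correlation).

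Under scaling by library size the medians of these lists moved to -0.08 for gluconeogenesis, -0.11 for bile acid, -0.17 for xenobiotic, -0.07 for urea cycle, -0.02 for hepatocyte identity and -0.21 for red cell genes, and to 0.05 for fatty acid oxidation genes. On log2(TPM + 1) the medians were 0.07 for fatty acid oxidation and 0.04 for hepatocyte identity genes and negative for the other 5 lists. Camera compares a list with other genes, and library size moved the log2 fold changes of all genes alike. Its adjusted p still changed, from 0.00281 to 2.25e-05 for xenobiotic genes, so its p depends on the scaling. The calls under library size are no separate test of these lists. On log2(TPM + 1) camera at the preset correlation placed the 7 lists lower than other genes, with adjusted p from 5.55e-06 (xenobiotic) to 0.00604 (hepatocyte identity). The 100 most abundant transcripts of control liver outside all lists had a median log2 fold change of -0.34, and markers of T and NK cells and of stellate cells were higher in the same livers, with medians of 0.69 and 0.33. The fatty acid oxidation call was lost without Tox4 shRNA replicate 2 (adjusted p = 0.0663), where its median on log2 CPM went from -0.15 to -0.07. The red cell call was lost without control replicate 2 (0.101), control replicate 3 (0.124), Tox4 shRNA replicate 2 (0.0507) or Tox4 shRNA replicate 3 (0.0924), and the red cell median on log2 CPM went from -0.42 to -0.68 without control replicate 1 and -0.23 without control replicate 3. Of the 15 genes of these lists that fell and are followed across alternatives, 5, 4 and 5 kept their call without control replicates 1, 2 and 3, 7, 11 and 6 without Tox4 shRNA replicates 1, 2 and 3, and 7 with scaling by library size.

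Camera placed 5 lists higher in Tox4 shRNA livers, those of the interferon response, p53 targets, cell division, T and NK cells, and stellate cells and matrix. All 28 interferon response genes tested had a positive log2 fold change, 7 rose (19 adjusted over the list alone), and the median was 0.65 (camera adjusted p = 1.86e-11, and 0.403 with an estimated correlation). Among them, the chemokine Cxcl10 rose from 21.8 ± 2.22 to 41.4 ± 7.55 CPM (n = 3 per group, 0.92, SE 0.14, edgeR adjusted p = 0.0112). All 14 p53 target genes were positive, 5 rose (10 adjusted over the list alone), and the median was 0.70 (camera adjusted p = 1.20e-07, and 0.403 with an estimated correlation). They were Phlda3, the cyclin Ccng1 (0.62, SE 0.12, 0.0202), the apoptosis effector Bax (0.66, SE 0.14, 0.0277), the exonuclease Aen (0.75) and Zmat3 (0.65), the last named after its value was seen. Of 17 cell division genes, 4 rose (8 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 1.25e-05, and 0.497 with an estimated correlation). These were Top2a, the topoisomerase of dividing cells, from 7.71 to 18.1 CPM (1.23, SE 0.21, 0.0208), and the helicase subunits Mcm5 (1.23), Mcm6 (1.23) and Mcm2 (1.01). On log2 CPM the cell division median was 0.84, and 0.52 without control replicate 3 (camera adjusted p = 1.11e-04), which also stood apart on the first principal component (-35.9, against -15.1 and -13.9 for control replicates 1 and 2). All 15 markers of T and NK cells were positive, 3 rose (7 adjusted over the list alone), and the median was 0.69 (camera adjusted p = 2.00e-05, and 0.403 with an estimated correlation). Those that rose were the perforin gene Prf1 (1.23, SE 0.28, 0.0328), the NK receptor gene Klrk1 (0.52, SE 0.12, 0.0364) and Cd8b1 (0.82, SE 0.21, 0.0471). Of 13 markers of stellate cells and matrix, 1 rose (4 adjusted over the list alone), Acta2, with a median of 0.33 (camera adjusted p = 0.0218, and 0.577 with an estimated correlation). The stellate cell call was lost without control replicate 1 (0.0737), control replicate 2 (0.105) or Tox4 shRNA replicate 1 (0.0992), where its median on log2 CPM went from 0.34 to 0.18, 0.22 and 0.28, with scaling by library size (0.102) and on log2(TPM + 1) (0.182). Of 17 followed genes of these lists that rose, 3, 7 and 10 kept their call without control replicates 1, 2 and 3, and 9, 13 and 9 without Tox4 shRNA replicates 1, 2 and 3.

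**Figure D3:**
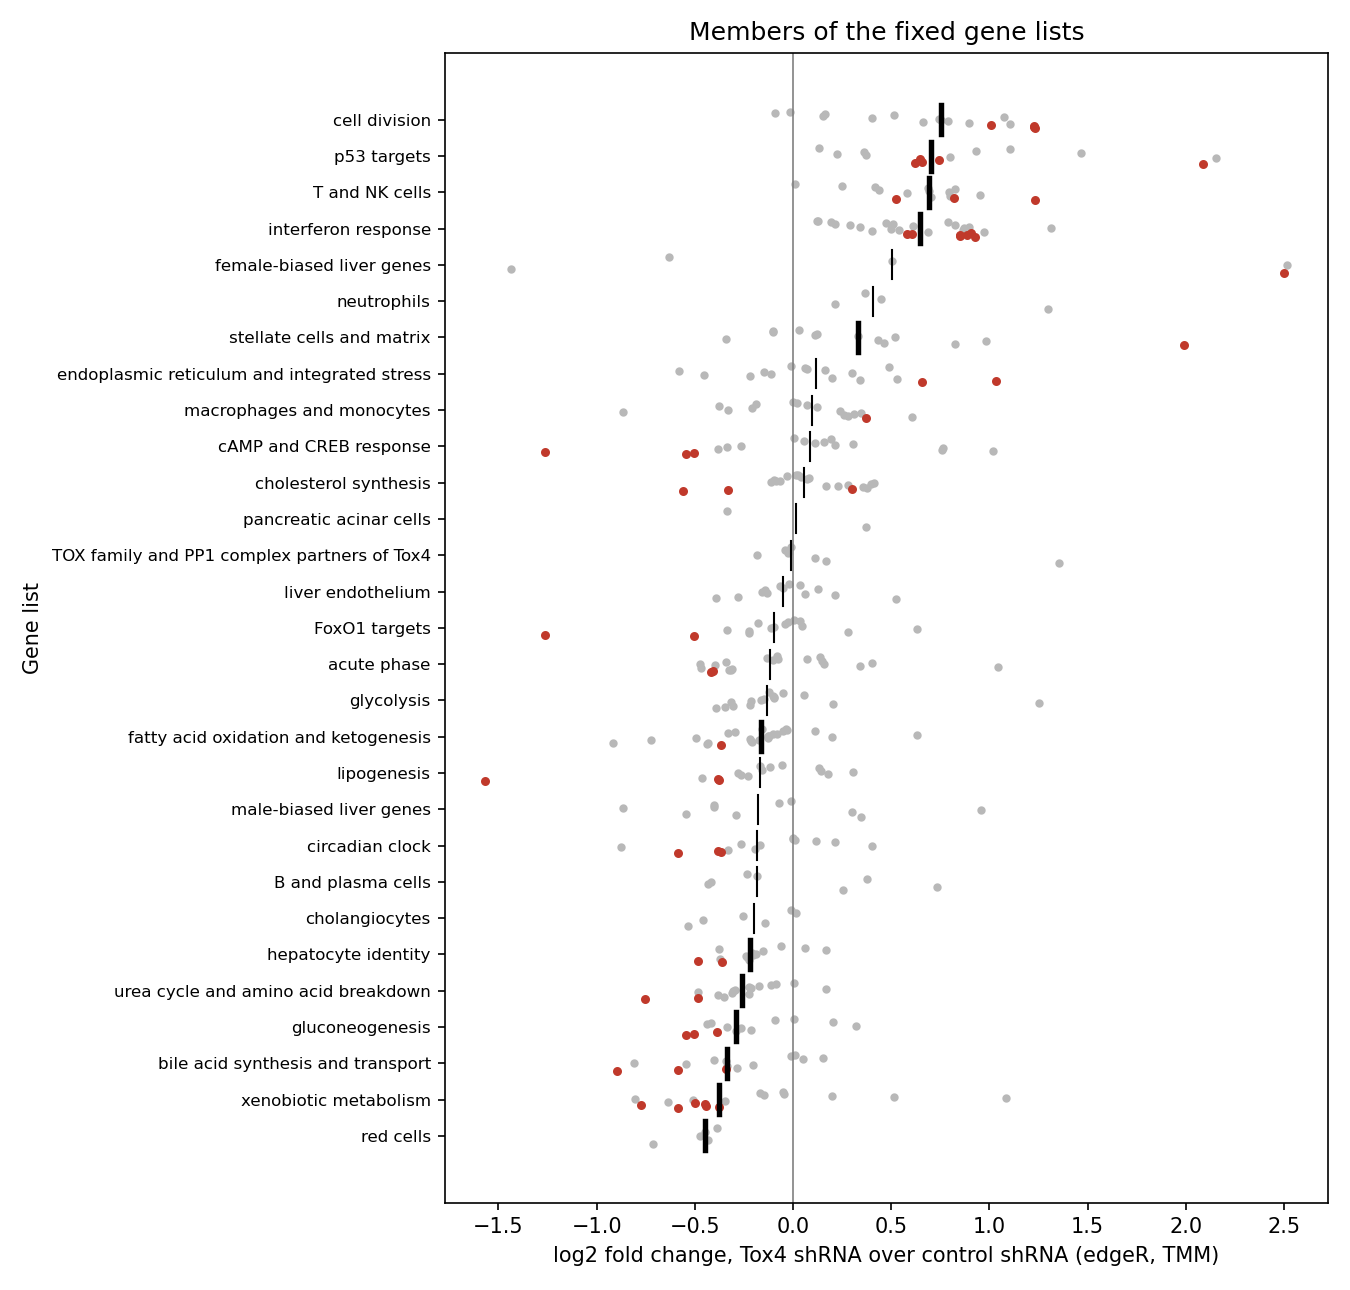
Log2 fold change of each tested member of the 29 gene lists (points, red where the edgeR adjusted p was under 0.05), with the median of each list as a black line, drawn thick where the camera adjusted p was under 0.05. All 28 interferon, 14 p53 and 15 T and NK cell genes lie above 0, while the medians of 7 lists that passed lie below it.

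Further metabolic and regulatory lists did not pass. Of 15 lipogenesis genes, 3 fell (4 adjusted over the list alone), namely Scd1, the desaturase Fads1 (-0.38) and the malic enzyme Me1 (-0.38), with a median of -0.17 (camera adjusted p = 0.0617). Of 14 circadian clock genes, 3 fell (4 adjusted over the list alone), the output factors Dbp (-0.58) and Tef (-0.37) and the period gene Per3 (-0.38), with a median of -0.18 (0.0589). None of 16 glycolysis genes passed (2 fell adjusted over the list alone), with a median of -0.14 (0.0617). Of 20 acute phase genes, 2 fell (4 adjusted over the list alone), the fibrinogen chains Fgb (-0.42) and Fgg (-0.41), with a median of -0.12 (0.123). Of 15 FoxO1 targets, Pck1 and Irs2 fell (2 adjusted over the list alone), with a median of -0.10 (0.102). Of 16 cAMP and CREB response genes, Ppargc1a, Pck1 and Irs2 fell and none rose (3 fell and 1 rose adjusted over the list alone). Their median was 0.08 and their mean 0.02 while camera placed the list downwards (0.664), with adjusted p up to 0.901 over the alternatives. On log2(TPM + 1) camera called the list lower than other genes (0.0276) although its median there was 0.25, and without control replicate 3 the median on log2 CPM turned from 0.10 to -0.11 (0.275). Of 20 cholesterol synthesis genes, Hmgcs1 rose (0.30) and Stard4 (-0.56) and Sc5d (-0.33) fell (3 rose and 2 fell adjusted over the list alone), with a median of 0.06 (0.346). Of 16 endoplasmic reticulum and integrated stress genes, Creld2 (0.66) and Atf3 (1.03) rose (3 adjusted over the list alone), with a median of 0.12 (0.230). The 10 male-biased liver genes had a median of -0.18 (0.716), and of 5 female-biased genes Cyp3a41a rose, at 0.0672 and 0.406 CPM (1 adjusted over the list alone), with a median of 0.51 (0.238). Without Tox4 shRNA replicate 3 both medians changed sign on log2 CPM, the male-biased median from -0.19 to 0.04 and the female-biased median from 0.33 to -0.05, and the latter was 0.85 without Tox4 shRNA replicate 1.

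Some of these lists passed with camera when 1 library was left out. Lipogenesis passed without control replicate 3 (adjusted p = 0.00937), Tox4 shRNA replicate 2 (0.0237) or Tox4 shRNA replicate 3 (0.0293), and circadian genes passed without the same libraries (0.0368, 0.0276 and 0.0371). Glycolysis passed without control replicate 1 (0.00934) or Tox4 shRNA replicate 2 (0.0340), acute phase genes without control replicate 3 (0.0103) or Tox4 shRNA replicate 2 (0.0210), and FoxO1 targets without control replicate 3 (0.0254) or Tox4 shRNA replicate 1 (0.0107). On log2 CPM the lipogenesis median went from -0.15 to -0.25 without control replicate 3, the glycolysis median from -0.13 to -0.24 without control replicate 1, and the circadian median from -0.18 to -0.11 without Tox4 shRNA replicate 1. The acute phase median went from -0.18 to -0.32 without Tox4 shRNA replicate 2, -0.08 without control replicate 2 and -0.06 without Tox4 shRNA replicate 3, and the FoxO1 target median from -0.10 to -0.06 without control replicate 1 and -0.15 without Tox4 shRNA replicate 1. With voom weights lipogenesis (0.0274), glycolysis (0.0423) and circadian genes (0.0214) passed, and with no filter beyond a count above 0 glycolysis and circadian genes did (both 0.0450). On log2(TPM + 1) camera called lipogenesis (0.00842), acute phase and circadian genes (both 0.0265) lower than other genes, although their medians there were 0.03, 0.13 and 0.09. With scaling by library size the medians of lipogenesis, circadian, acute phase, glycolysis and FoxO1 target genes turned to 0.05, 0.03, 0.02, 0.08 and 0.11, while camera called the first 3 of these lists lower than other genes (adjusted p = 0.0133, 0.0291 and 0.0240). These calls are no separate test either, because library size moved the log2 fold changes of all genes alike. The camera adjusted p still changed with the scaling, for lipogenesis from 0.0617 to 0.0133. Over all alternatives, the highest adjusted p of these 5 lists ran from 0.403 to 0.708. Of 14 followed genes of these lists and of the remaining lists, 3, 3 and 3 kept their call without control replicates 1, 2 and 3, and 4, 9 and 3 without Tox4 shRNA replicates 1, 2 and 3.

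The other partners of Tox4 and the other cell types were also examined. None of 7 tested genes of the TOX family and the PP1 complex passed, over all genes or over the list alone, with a median of -0.01, a mean of 0.20 and an upward camera direction (adjusted p = 0.531). Ppp1r10, which encodes the PP1 subunit PNUTS that binds Tox4, measured 32.0 ± 13.2 CPM in control and 81.7 ± 24.9 CPM in Tox4 shRNA livers (n = 3 per group). Its log2 fold change of 1.36 (SE 0.42) did not pass in edgeR (adjusted p = 0.163), was higher in 3 of 3 Tox4 shRNA livers than in any control liver, and passed in DESeq2 (0.0216) and limma voom (0.0413), with 0.00125 to 0.326 over all alternatives. Of 16 markers of macrophages and monocytes, the complement gene C1qc rose (0.37, SE 0.10, edgeR adjusted p = 0.0475, and 2 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.328). This list passed without Tox4 shRNA replicate 2 (0.0224), where its median on log2 CPM went from 0.07 to 0.22, and its median turned to -0.08 with a downward camera direction without Tox4 shRNA replicate 1 (0.757). The 4 neutrophil markers had a median of 0.41 (0.106) and passed without control replicate 1 (0.00442), where the median on log2 CPM went from 0.46 to 0.72, against 0.29 without control replicate 3 and 0.20 with no filter. With fry the neutrophil, gluconeogenesis and xenobiotic lists were the 3 that passed (adjusted p = 0.0436 for each). Of the 10 neutrophil markers listed only 4 were tested, and 1 reached a mean of 1 CPM in control liver. The 13 liver endothelium markers had a median of -0.05 and a mean of -0.02 with an upward camera direction (0.964), and passed without control replicate 3 (0.0344). Their median on log2 CPM turned from -0.02 to 0.18 in that fit and to 0.11 without Tox4 shRNA replicate 2, and was -0.18 without control replicate 1. The 6 cholangiocyte markers had a median of -0.20 (0.215) and passed without Tox4 shRNA replicate 3 (0.0203), where the median on log2 CPM went from -0.24 to -0.39, against -0.13 without Tox4 shRNA replicate 1. The 7 B and plasma cell markers had a median of -0.18 and a mean of 0.01 (0.964), and the 2 pancreatic acinar markers a median of 0.02 (0.805), and both medians on log2 CPM changed sign without Tox4 shRNA replicate 2. Among these 6 cell types, C1qc was the one marker that passed over all genes, and none passed over the list alone outside the macrophage list.

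Single transcripts were tested to ask whether isoforms of the same genes moved. Of 35517 transcripts, 0 passed in edgeR, the smallest adjusted p was 0.0837, and 3509 had an unadjusted p under 0.05. DESeq2 called 955 transcripts, 414 up and 541 down, and limma voom called 3. The main Ppp1r10 transcript, ENSMUST00000087210.6, had a log2 fold change of 1.43 (edgeR adjusted p = 0.315).

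The comparison deposited by the authors was set beside the edgeR test. It lists 667 genes, 450 higher and 217 lower in Tox4 shRNA livers, with log2 fold changes of at least 0.50 in size and unadjusted p up to 0.0118. Tox4 itself is listed at -0.55 and Ppp1r10 at 1.42. Of the 664 listed genes tested here, 664 had the same direction and 423 passed in edgeR. The threshold of the deposited list is not stated and may be looser than the edgeR one. Limma voom here called 672 genes at an adjusted p under 0.1 and at least the smallest listed fold. Its log2 fold changes differed from the listed ones by a median of 0.00278 in size. Of the 334 genes that passed in edgeR and are not listed, 318 had smaller log2 fold changes than any listed gene. Both comparisons use the same 6 libraries, so the overlap is not independent evidence.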

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

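Thinning to the smallest library was chosen after the data were seen, and the other alternatives were set in advance. Depth limits genes of low abundance, and at 3 livers per group many changes under 2-fold would be missed. Tox4 stayed lower in all 18 fits, in 11 of them past the threshold. Scaling set the balance of directions. With library size alone 2435 genes changed (2327 up, 108 down) and the Tox4 log2 fold change was -0.33. Limma gave 1916 (1873 up, 43 down) and a Tox4 change of -0.22 on log2(TPM + 1), 1900 (1857 up, 43 down) and -0.25 on log2(TPM + 0.1), and 0 genes (0 up, 0 down, 5026 at an unadjusted p under 0.05 of 20574 tested) and -0.22 with no filter. On these scales the median gene moved by 0.21 (library size), 0.23, 0.26 and 0.21.

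DESeq2 called 1214 genes (586 up, 628 down), and with no filter edgeR raised 574. DESeq2 made more false calls than edgeR on simulated data, and otherwise the cause was not tested. An adjusted p under 0.01 gave 52 genes (30 up, 22 down), an adjusted p under 0.1 gave 1575 (792 up, 783 down), and a fold of at least 1.5 at an adjusted p under 0.05 gave 324 (238 up, 86 down). Leaving out 1 library, which also leaves fewer samples, gave 154 to 612 genes, 78 to 304 up and 76 to 308 down, and a Tox4 change of -0.65 to -0.43. The lowest count, 154, came without control replicate 1, and the counts without control replicates 2 and 3 and Tox4 shRNA replicates 1 and 3 were 172, 230, 477 and 284. Thinned libraries gave 714 genes.

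With the replicate block 797 genes changed (424 up, 373 down, 599 shared with the fit without it), 11 lists passed, and Tox4 was at -0.54. The numbers showed no clear pairing of the libraries and no label explains them, so the block has no known meaning. With a correlation estimated per list 0 lists passed, and with fry 3. Leaving out 1 library gave 10 to 16 lists. For transcripts, 3 passed in edgeR with no filter, 955 in DESeq2 and 3 in limma voom, against 0 in the other alternatives. The cause was not tested.

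Of the genes named, 81 passed, and 28, 30 and 39 of them kept their call without control replicates 1, 2 and 3, and 50, 60 and 45 without Tox4 shRNA replicates 1, 2 and 3. Library size kept 64, DESeq2 80, limma voom 69, robust=FALSE 66 and the replicate block 64. On log2(TPM + 1) 48 were kept, on log2(TPM + 0.1) 47, and with no TPM filter 0. The direction turned for Crtc2 (0.0298, 0.0305 and 0.0298), Foxo1 (0.0432, 0.0488 and 0.0432) and Insr (0.0878, 0.0907 and 0.0878) on log2(TPM + 1), log2(TPM + 0.1) and with no TPM filter, none of which had passed, and for Rad54l with no TPM filter (-0.0453). With 1 library left out Creb1 ran from -0.0714 to 0.13 and Igfbp1 from -0.24 to 0.45. The shift of the median gene on the TPM scale is larger than each of the values of Crtc2, Foxo1 and Insr there.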

Other observations

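The gene groups in this paragraph and the next, and the tests of fewer hepatocytes and of 1 library, were chosen after the results were seen, so their p-values are descriptive. The camera p-values of these groups are unadjusted, unlike those given for the 29 lists. With an estimated correlation, the unadjusted camera p was 0.04996 for the xenobiotic and 0.0581 for the gluconeogenesis list, and neither list passed once adjusted. Of 16 genes of the actin cytoskeleton, 12 rose in Tox4 shRNA livers, with a median log2 fold change of 0.60 (camera p = 1.28e-13, and 0.0306 with an estimated correlation). The nonmuscle myosin Myh10 rose from 15.7 ± 1.28 to 26.9 ± 1.49 CPM (n = 3 per group, 0.77, SE 0.09, edgeR adjusted p = 0.00481), and the actin-binding Tmsb10 rose from 13.9 ± 0.914 to 28.7 ± 4.90 CPM (1.04, SE 0.13, 0.00481). Of 8 genes of MHC class II antigen presentation, 7 rose, with a median of 0.81 (camera p = 4.63e-08, and 0.0631 with an estimated correlation). H2-Eb1 rose from 118 ± 10.6 to 205 ± 23.8 CPM (0.80, SE 0.10, 0.00521), and Ciita, the transactivator of these genes, rose from 10.5 ± 1.71 to 20.9 ± 2.28 CPM (0.98, SE 0.13, 0.00659). In the same livers the markers of T and NK cells had a median of 0.69 and those of stellate cells and matrix 0.33, with Acta2 at 1.99. Markers of macrophages and monocytes had a median of 0.10 and those of B and plasma cells -0.18, and neither of these lists passed (camera adjusted p = 0.328 and 0.964).

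Of 12 replication licensing genes, 6 rose, with a median of 0.84 (camera p = 1.89e-07, and 0.0976 with an estimated correlation), among them Mcm3 (1.08, SE 0.19, edgeR adjusted p = 0.0151), and part of this group is in the cell division list. Of 10 heat shock genes, the chaperone Hsp90aa1 rose (0.64, SE 0.10, 0.0112), and the inducible Hspa1b, which has a close paralog, measured 19.8 ± 8.78 and 87.8 ± 20.5 CPM without passing in edgeR (2.16, SE 0.38, 0.0502). Hspa1b passed in DESeq2 (2.40e-05), limma voom (0.0137) and without control replicate 3 (0.0147), and over all alternatives its adjusted p ran up to 0.152. The median of this group was 0.55 (camera p = 1.64e-04, and 0.0998 with an estimated correlation). Of 14 hepatocyte nuclear receptor genes, 3 fell, namely Nr1i3, the xenobiotic receptor CAR, from 488 ± 42.6 to 292 ± 34.7 CPM (-0.74, SE 0.11, 0.00804), Nr1h5 (-0.94, SE 0.20, 0.0255) and Rxra (-0.36, SE 0.08, 0.0333). The median of this group was -0.12 (camera p = 0.00312, and 0.0348 with an estimated correlation). Of 13 followed genes of these groups, 8, 8 and 9 kept their call without control replicates 1, 2 and 3, and 12, 11 and 11 without Tox4 shRNA replicates 1, 2 and 3.

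A smaller share of hepatocytes was weighed as a source of the lower metabolic lists. With the mix of other cells unchanged, it would raise the markers of every other cell type alike. T and NK cell markers lay above liver endothelium markers by a difference of medians of 0.74 (permutation of genes, p = 4e-05). This argues against such a share as the whole explanation, but not against a share lowered by incoming T and NK cells. The p of this difference takes markers that vary together as independent and measures no spread between livers. Without control replicate 3 this difference fell to 0.40 (permutation p = 0.00358), with medians of 0.60 for T and NK cells, 0.52 for stellate cells and 0.20 for endothelium, so a smaller share as part of the change is not excluded. After thinning to the smallest library 14 of the 15 followed list members that fell were still called, which argues against depth for these members. They are the ones named by the rule, up to 4 per list with the smallest p, and not all list members that fell. With scaling by library size 7 of the 15 were still called, and on log2(TPM + 1) 2 were. Library size moved all genes alike (SD of the shift over genes 0.00471 log2). For members that lost their call, a fall thus cannot be told apart from the scaling. The metabolic genes had a median 0.0633 above that of the 100 most abundant other transcripts, -0.34 (permutation of genes, p = 0.103). They thus fell no more than these 100 transcripts, which were not matched to them in abundance. The most abundant 10% of all tested genes had a median of -0.13, a smaller fall than that of the 100. The comparison with the 100 cannot tell dilution of hepatocyte RNA by incoming cells from another cause of a fall in abundant transcripts. Dilution therefore remains open, and a direct effect of Tox4 on the metabolic genes was not tested.

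The higher interferon, p53 and T cell lists did not rest on 1 library, as over the 18 fits of these 3 lists without 1 library the lowest median was 0.735 of that with all 6, although none of the 3 passed with an estimated correlation (adjusted p = 0.403). The p53 list and the T and NK cell markers differed in median by 0.00722 (permutation p = 0.955), so whether p53 targets were brought in by T and NK cells cannot be told apart from a change within hepatocytes by this test, which compares sizes and not cells. The T and NK cell markers were scarce. The most abundant, in control and Tox4 shRNA livers, were Ccl5 (8.76 and 14.1 CPM), Gzmb (8.19 and 11.1 CPM) and Klrk1 (6.38 and 9.17 CPM). The p53 target Trp53inp1, named after its values were seen, measured 129 and 224 CPM. Of these genes, only Klrk1 passed the edgeR test over all genes. None of the T and NK cell marker genes is in another list, and 14 of the 15 reached 1 CPM in control liver. A response to the virus that differed between the vectors, an off-target effect of the shRNA and a response to lower Tox4 remain untested, since each group had 1 virus.

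Fam177a and its paralog Fam177a2 moved in opposite directions in the deposited comparison, at 5.29 and -4.82. The TPM of both genes summed to 1.37, 1.54 and 1.497 in control livers and 1.84, 1.80 and 1.94 in Tox4 shRNA livers, a log2 ratio of 0.34. A candidate explanation is reads shared between the paralogs, since the sum moved far less than either gene, and no biological explanation was tested.

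The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 757 genes and the highest of the others 2, it called 12 lists against 11 for the highest of the others, and it called 0 transcripts against 0. In each case the number of splits that gave a result as large, the real one included, was 1 for genes, 1 for lists and 10 for transcripts.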
